A study of Mus musculus with 16 samples.

How the data were processed

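Liver RNA of mice aged 7 weeks was compared on 16 two-colour Agilent oligonucleotide arrays. Each array held RNA of a pool of livers in one dye and RNA of another pool in the other dye, so each spot gives a ratio between 2 pools. The 4 RNA groups were wild-type males, wild-type females, HNF4alpha knockout males and HNF4alpha knockout females, all of 1 mixed strain background. The 4 comparisons had 4 arrays each, which were wild-type male against wild-type female, knockout male against knockout female, wild-type male against knockout male, and wild-type female against knockout female. The number of mice in a pool is not stated.

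Per the file headers, the deposited scanner files came from Feature Extraction 9.1.1.1 and hold spot brightness as intensity, given as mean pixel signal per channel with the median of the local background. Per the file headers, they also hold a log10 ratio of red over green after background subtraction and lowess dye normalization. The authors also deposited one log2 ratio per spot and array. On every array these values followed the log10 ratio rescaled to log2, with the sign kept on 8 arrays and turned on the other 8. Between 72.5% and 93.4% of spots matched within 0.01, which were 99.6% to 100% of the spots well above background in both channels and 15.7% to 45.1% of the others. What was done to the remaining spots is not stated. The median of the authors' log2 values ranged from -0.10 to 0.23 over the 16 arrays.

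The labels give the same dye to the first-named RNA on every array, while the study's design text describes dye-swapped pairs. Within a comparison, arrays as scanned correlated across genes from -0.92 to 0.90, so swaps were present. Each array was turned to one direction by the sign that the authors' values carry. The direction was then checked on Xist, on Y-linked genes and on Hnf4a. In that direction the first-named RNA was in green on replicates 1 and 3 of 3 comparisons and on replicates 2 and 4 of wild-type female against knockout female. Differences are reported as male minus female or as knockout minus wild type.

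The mean signals of both channels were background-corrected with normexp (offset 50) and normalized within each array by loess in limma 3.58.1 (R 4.3.3, with the data.table package at version 1.17.8). Spots marked as outliers in the deposited files were left out on the array concerned, and the 245 probes with more than 1 spot were averaged over their spots. A probe was tested if it was well above background in at least 1 channel on all 4 arrays of at least 1 comparison, which held for 31720 of 41174 probes. The gene of each probe came from the platform annotation. It gave 1 gene for 31700 probes, several for 47 and none for 9427, and 31564 probes matched a reference annotation by gene ID with no symbol changed. A gene was represented by its brightest tested probe, which was a choice among several for 6661 genes. The tests covered 22031 items, of which 16002 were genes with a symbol and 6029 were probes without one. Some genes were on no listed probe and were not analysed here, Ddx3y among them. Counts of genes include the probes without a symbol. No genomic positions are given because the files name no genome build.

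Each scan had between 68.5% and 92.2% of spots well above background per channel. The median spot signal was 334 to 563 in green and 440 to 699 in red, with 0 to 17 saturated spots per array and channel. The number of arrays limits the precision.

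The labels do not say which arrays form a dye-swapped pair. Replicates 1 and 2, and replicates 3 and 4, have opposite dye directions in every comparison and were averaged as pairs, which left 2 values per comparison. A linear model with 1 coefficient per comparison was fitted to the 8 pair means with limma, with empirical Bayes moderation and a mean-variance trend. P-values were adjusted over all items tested by the Benjamini-Hochberg method, and an adjusted p under 0.05 was taken as passing. The p-values measure the spread between pair means, not between individual mice. The difference of the knockout effect between the sexes (the interaction) was the mean of its estimates from the male against female arrays and from the wild type against knockout arrays. A positive interaction means a more positive knockout effect in males. These 2 estimates had a correlation across genes of 0.946, and the deviations of pair 1 closed the loop of the 4 comparisons with a correlation of 0.79. They are therefore not independent, and the SE of the interaction is understated, so its count is also given from either kind of array and from a fit on its own 2 pair values.

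The replicate number was also the slide (4 slides with 1 array of each comparison). Scan day 1 held slide 1, day 2 slide 2 and day 3 slides 3 and 4. Comparisons that share an RNA group had deviations that correlated at the same number in 16 of 16 cases (0.21 to 0.49) and best at the same number in 15 of 16, so the numbers link samples across comparisons. Fits with the slide as a block are given beside the results they change. These fits used the 16 arrays as separate replicates, with a dye term and part of the slide contrasts. The contrast of slides 1 and 3 against 2 and 4 could not be separated from the comparisons and was left out. They therefore adjust for the slide only in part, and their counts also reflect the loss of pair averaging and the dye term.

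Genes are named by a rule. For each comparison and for the interaction, the rule takes the 6 largest changes in each direction among genes that passed the test, had a proper symbol and were measured in both groups. For the 4 comparisons these also had the same sign on all 4 arrays. It adds up to 2 genes in each direction with the largest lower bound on the fold where 1 of both groups was not well above background. Hnf4a, Xist, Eif2s3y, Kdm5d and Uty are always named, and each gene list adds up to 4 members with the smallest p. For such a bound the dim group was set, on each array, to the level of the dimmest spot called well above background wherever its own level was lower.

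The 31 gene lists cover sex-biased liver genes, liver functions and markers of cell types. They were tested with limma's camera with a preset correlation of 0.01 and adjusted over the 31 lists of a comparison. Camera asks whether a list moved more than the other genes. It was also run with the correlation estimated from the data, and fry, which asks only whether a list's genes move on balance in one direction, was run as an alternative. Lists of skeletal muscle transcripts (15 of 18 measured) and of further pancreas transcripts (15 of 17 measured) were written after the first results were seen and were not tested with camera. Correlations between comparisons are across genes, which are not independent replicates. Overlaps of comparisons without a shared RNA group were compared with the number that independent lists would share.

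The fit was tested on simulated data with 200 of 22031 items changed, 50 at each fold, and no others. It recovered 80% to 84% of genes changed 1.5-fold, 94% to 100% at 2-fold and 8% to 20% at 1.2-fold, with 4 to 7 false calls per comparison. Of 30 simulated lists of 20 genes, the 1 shifted list passed and 0 others did. The simulated noise was drawn independently for each gene and array. The simulation therefore does not show how many false calls arise where genes are correlated or arrays are linked by replicate number.

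Alternatives covered the normalization (the deposited log10 ratios, the authors' log2 values, no background subtraction, an offset of 10, median centring), the probe filter, the mean over probes, the model (separate arrays, a dye term, blocks for slide or pair, a loop model, no trend), the other pairing of arrays, the thresholds, single kinds of arrays for the interaction, and each array left out in turn. Added after the data were seen were a fit of each comparison alone and leaving out 2 arrays flagged for their spots. So were requiring a call with both pairings and testing lists without the genes they share with the sex-biased lists. Of the 2 flagged arrays, replicate 1 of wild-type female against knockout female had 1338 outlier spots. Replicate 1 of knockout male against knockout female had the highest share of spots well above background.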

Results

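Liver gene expression was compared between male and female mice that were wild type or carried a knockout of HNF4alpha, a nuclear receptor that drives many hepatocyte genes. RNA of pooled livers was measured on 16 two-colour arrays, 4 for each of 4 comparisons, and the 4 arrays were averaged to 2 dye-swapped pairs. Changes are log2 differences ± SE of the limma model (n = 2 pairs of arrays per comparison). A gene is said to differ, rise or fall only if its adjusted p was under 0.05. The number of arrays limits the precision. Genes named as the largest changes of a comparison had the same sign on all 4 of its arrays, and so did the median of a list that passed camera, the list test, in a comparison, unless another number of arrays is given.

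Hnf4a itself fell by 1.02 ± 0.05 in knockout males (adjusted p = 7.92e-06) and by 1.02 ± 0.05 in knockout females (adjusted p = 1.10e-05). The single arrays ranged from -1.12 to -0.88 in males and from -1.19 to -0.95 in females. Dimmer probes of Hnf4a gave 0.77 and -0.63 in males and 0.57 and -0.53 in females, and where each probe lies relative to the deleted part is not known here. Hnf4a did not pass the test between the sexes, with -0.01 ± 0.05 in wild type and -0.03 ± 0.05 in the knockout. Xist and the Y-linked genes differed between the sexes in the labelled direction in both genotypes.

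Transcripts of other tissues appeared on some arrays. Skeletal muscle transcripts (15 measured) had medians of 2.21 and 2.04 on arrays 2 and 3 of knockout male against knockout female, and of 0.20 and 0.22 on arrays 1 and 4. Against wild-type males, knockout males showed muscle medians of 1.42 and 1.54 on arrays 2 and 3 and of 0.20 and -0.01 on arrays 1 and 4. Pancreas transcripts of the list written later (15 measured) had medians of 2.37 and 2.76 on arrays 3 and 4 of the knockout effect in females, and of -0.07 and -0.00 on arrays 1 and 2. The same list had medians of -2.90 and -2.70 on arrays 3 and 4 of knockout male against knockout female. In wild-type male against wild-type female, the muscle medians lay between -0.05 and 0.09. The pairs used here each contain 1 of the 2 arrays with muscle transcripts, so a call that also holds with the other pairing (replicates 1 with 4 and 2 with 3) is given beside the counts.

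**Figure D1:**
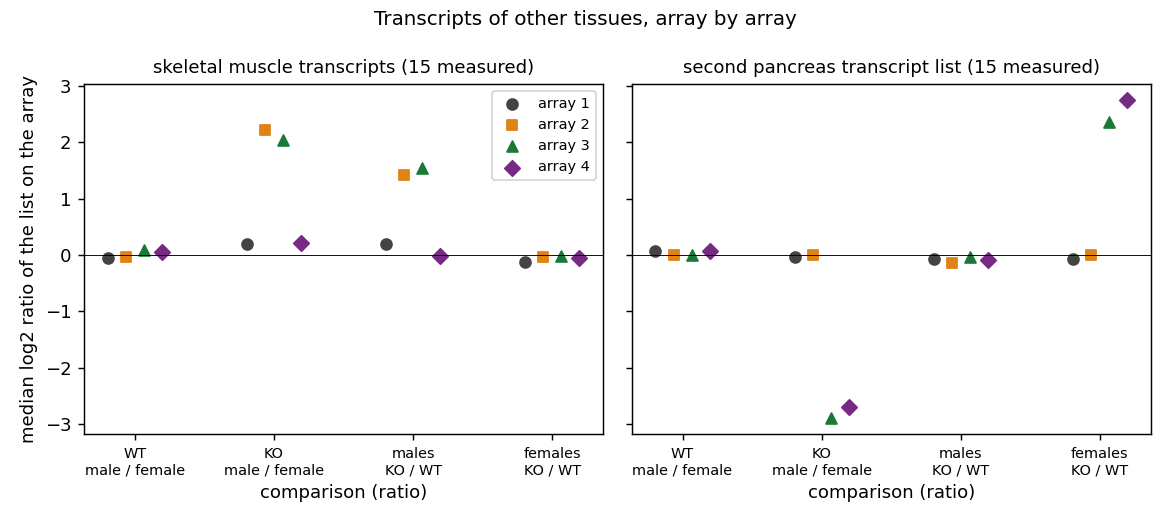
Median log2 ratio of 15 skeletal muscle transcripts (left) and of 15 pancreas transcripts (right) on each array (symbols) of each comparison (x axis). Muscle medians exceed 1 only on arrays 2 and 3 of the comparisons with knockout male RNA, and pancreas medians exceed 2 in size only on arrays 3 and 4 of the comparisons with knockout female RNA.

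The comparison of wild-type males with wild-type females asks which liver genes differ by sex. The sex-biased genes that the lists hold differed in their listed direction almost throughout. Both lists come from general knowledge of growth-hormone-regulated mouse liver genes, part of it from work of the same field. Their p-values here are therefore not an independent test of these sex differences. In the list of male-biased liver genes, 20 of 23 measured members were higher in males, 0 were lower and 3 did not pass (21 passed adjusted over the list alone). They included the fatty acid elongase Elovl3 (3.81 ± 0.12), the complement component C6 (2.93 ± 0.08), the steroid dehydrogenase Hsd3b5 (2.63 ± 0.08) and Cspg5 (2.46 ± 0.08). In the list of female-biased genes, 24 of 26 were higher in females, 0 were lower and 2 did not pass (25 passed adjusted over the list alone). Among them were the organic anion transporter family member Slc22a26 (-5.04 ± 0.11), the plasma protein gene A1bg (-4.32 ± 0.12) and the nuclear cofactor Trim24 (-1.41 ± 0.05). Camera gave an adjusted p of 2.5e-26 for the male-biased list and of 2.8e-27 for the female-biased list (adjusted p = 0.0085 and adjusted p = 0.010 with an estimated correlation), and both list medians had the same sign on 4 of 4 arrays.

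Sex chromosome genes and sulfotransferases were among the largest differences. Eif2s3y (6.13 ± 0.15, adjusted p = 6.0e-06), Kdm5d (3.50 ± 0.13) and Uty (3.38 ± 0.24, with females well above background on 2 of 4 arrays), all Y-linked, were higher in males, and Xist (-6.10 ± 0.16), which silences the X chromosome, was higher in females. The sulfotransferases Sult3a1 (-7.94 ± 0.35, adjusted p = 3.7e-05), Sult2a4 (-5.17 ± 0.33) and Sult2a2 (-4.83 ± 0.18) and the hydroxyacid oxidase Hao2 (-5.67 ± 0.21) were higher in females. Nat8f5 (4.08 ± 0.16) and the oxysterol hydroxylase Cyp7b1 (3.25 ± 0.13) were higher in males. Trav14d-3-dv8 was at least 1.36-fold and Slc35f1 at least 1.33-fold higher in males, since neither was well above background in females. Of the 8 measured genes of the sex chromosome list, 3 were higher and 4 lower in males (8 passed adjusted over the list alone). As a list they moved in no one direction by camera (adjusted p = 0.71, and 0.0066 with the slide as a block, with a median of -0.28 and a mean of 0.66).

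Other groups differed in part of their members. In the growth hormone and STAT5 list, 1 gene was higher and 5 lower in males of 16 measured (8 passed adjusted over the list alone). The repressor Bcl6 (0.89 ± 0.12) was higher in males, while the female-biased repressor Cux2 (-1.74 ± 0.18), the IGF carrier subunit Igfals (-0.36 ± 0.05) and the oestrogen receptor Esr1 (-1.25 ± 0.25) were lower (camera adjusted p = 0.069, 0.030 with the slide as a block, and 0.014 with the other pairing). Of 18 complement genes, 6 were higher in males, C8a by 1.11 ± 0.08 and C9 by 1.89 ± 0.15 among them, and the lectin gene Mbl2 was lower (-1.20 ± 0.07), while 11 passed adjusted over the list alone. Camera gave an adjusted p of 0.0091 for complement (adjusted p = 0.92 with an estimated correlation, 0.076 with the other pairing, and 0.15 without the 2 genes it shares with the sex-biased lists), and the list median of 0.16 turned to -0.06 with median centring. Of 21 bile acid genes, 6 were higher in males, Cyp8b1 of cholic acid synthesis among them (1.14 ± 0.08), and 4 were lower, with the transporter Slco1a4 at -1.90 ± 0.12 (13 passed adjusted over the list alone, camera adjusted p = 0.069). Of 19 acute phase genes, 3 were higher in males and 5 lower, the metallothioneins Mt2 (-2.72 ± 0.16) and Mt1 (-1.83 ± 0.15) and the orosomucoid Orm3 (-1.50 ± 0.13) among the latter (12 passed adjusted over the list alone, camera adjusted p = 0.26). Of 23 conjugation genes, 3 were higher in males, with the glucuronosyltransferase Ugt2b5 at 0.97 ± 0.11, and 6 were lower, with the sulfotransferase Sult1c2 at -0.94 ± 0.06 (15 passed adjusted over the list alone, camera adjusted p = 0.90).

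Lymphocyte and macrophage markers were lower in wild-type males, while 0 of 9 neutrophil markers passed (0 adjusted over the list alone, camera adjusted p = 0.87). Of 13 lymphocyte markers, 8 were lower in males and 0 higher (10 passed adjusted over the list alone), including the T cell receptor subunits Cd3d (-0.66 ± 0.08) and Cd3g (-0.55 ± 0.09) and the chemokine Ccl5 (-1.21 ± 0.22). Of 12 macrophage markers, 3 were lower (5 passed adjusted over the list alone), which were Cd163 (-0.48 ± 0.10), Cd5l (-0.49 ± 0.10) and Timd4 (-0.46 ± 0.09). Of 24 cell cycle genes, 2 were lower in males (2 passed adjusted over the list alone), the cyclin Ccnd1 (-1.57 ± 0.19) and the replication clamp Pcna (-0.33 ± 0.06). Camera gave adjusted p-values of 9.5e-05 for lymphocytes, 0.00028 for macrophages and 9.5e-05 for the cell cycle. With an estimated correlation these became adjusted p = 0.18, adjusted p = 0.94 and adjusted p = 0.94. No gene of cholesterol biosynthesis passed in 18 measured (0 adjusted over the list alone), while the list as a whole was higher in males, with a median of 0.37 and the same sign on 3 of 4 arrays (camera adjusted p = 0.0091, and adjusted p = 0.94 with an estimated correlation). Of 16 genes of fatty acid and triglyceride synthesis, 2 were lower in males (2 adjusted over the list alone), with the lipid droplet protein Pnpla3 at -2.33 ± 0.13 (camera adjusted p = 0.027, 0.11 with the slide as a block, and adjusted p = 0.94 with an estimated correlation).

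In all, 2323 of 22031 items differed between wild-type males and females, 1186 higher and 1137 lower in males, and 252 of them differed at least 2-fold (157 and 95). With the slide as a block, where arrays were separate replicates and a dye term was added, 5584 passed. In a fit of this comparison alone 1455 passed, and 2080 passed with both pairings. Higher in males were 51.1% of those that passed, and 35.1% with median centring.

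The effect of the knockout in males asks what HNF4alpha deletion does to the male liver. Genes of secreted and metabolic liver functions fell together. Of 18 complement genes 15 fell and 0 rose (15 passed adjusted over the list alone), with C8a at -4.66 ± 0.08, C8g at -3.41 ± 0.09 and C6 at -2.87 ± 0.08 (camera adjusted p = 3.6e-08, and adjusted p = 0.15 with an estimated correlation). Of 17 genes of lipid transport 13 fell and 2 rose (16 passed adjusted over the list alone). The apolipoprotein Apom stood at -3.54 ± 0.05, Apoa2 at -3.15 ± 0.08 and Apoc2 at -2.79 ± 0.09 (camera adjusted p = 1.2e-05, and adjusted p = 0.085 with an estimated correlation). Of 19 coagulation genes 15 fell and 3 rose (18 passed adjusted over the list alone), with the clotting factors F11 at -3.61 ± 0.09, F13b at -3.47 ± 0.09 and F12 at -3.19 ± 0.11 (camera adjusted p = 0.00017, and adjusted p = 0.085 with an estimated correlation). Of 21 bile acid genes 13 fell and 5 rose (18 passed adjusted over the list alone). The conjugating enzyme Baat stood at -4.46 ± 0.11, Cyp7b1 at -4.64 ± 0.13 and Cyp8b1 at -3.19 ± 0.08 (camera adjusted p = 0.0076, and adjusted p = 0.53 with an estimated correlation).

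Intermediary metabolism fell as well in knockout males. Of 20 genes of amino acid catabolism 14 fell and 2 rose (16 passed adjusted over the list alone), with the kynurenine pathway enzymes Kmo (-3.40 ± 0.08) and Haao (-3.25 ± 0.10) among them (camera adjusted p = 9.7e-05, and adjusted p = 0.50 with an estimated correlation). Of 18 genes of cholesterol biosynthesis 15 fell and 0 rose (15 passed adjusted over the list alone), with Sc5d at -2.29 ± 0.15 and Insig1 at -1.86 ± 0.15 (camera adjusted p = 7.9e-05, and adjusted p = 0.60 with an estimated correlation). Of 12 genes of glucose handling 8 fell and 1 rose (9 passed adjusted over the list alone). The glycogen synthase Gys2 stood at -3.34 ± 0.12 and the pyruvate carboxylase Pcx at -2.76 ± 0.10 (camera adjusted p = 0.019, and adjusted p = 0.25 with an estimated correlation). Of 16 genes of fatty acid synthesis 10 fell and 3 rose (13 passed adjusted over the list alone), with Elovl5 at -1.70 ± 0.09 and Pnpla3 at 1.37 ± 0.13 (camera adjusted p = 0.038, and adjusted p = 0.61 with an estimated correlation). Of 7 urea cycle genes 5 fell, the ornithine transcarbamylase Otc by 4.91 ± 0.11, and 1 rose (6 passed adjusted over the list alone, camera adjusted p = 0.13). Of 17 liver-enriched transcription factors 13 fell and 1 rose (14 passed adjusted over the list alone). The xenobiotic receptor Nr1i3 stood at -3.28 ± 0.08 and Ppara at -1.67 ± 0.10. Camera gave an adjusted p of 0.0018 for these factors (adjusted p = 0.28 with an estimated correlation), and their median of -0.31 turned to 0.06 with median centring.

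Hepatocyte identity markers moved in both directions in knockout males. Of 10 general hepatocyte markers 7 fell and 3 rose (10 passed adjusted over the list alone), with transthyretin, Ttr, at -3.20 ± 0.09 and the antitrypsin gene Serpina1b at -3.76 ± 0.19 (camera adjusted p = 0.071). Of 7 periportal markers 5 fell and 1 rose (6 passed adjusted over the list alone), with Cyp2f2 at -4.69 ± 0.18 (camera adjusted p = 0.035, 0.052 with the slide as a block, and adjusted p = 0.57 with an estimated correlation). Of 11 pericentral markers 5 fell, with Cyp1a2 at -1.38 ± 0.17, and 2 rose, with the glutamine synthetase Glul at 0.30 ± 0.05 (adjusted p = 0.0029, and 0.079 with the other pairing, 7 passed adjusted over the list alone, camera adjusted p = 0.64). Of 23 conjugation genes 13 fell, with Sult1b1 at -4.30 ± 0.14, and 7 rose (20 passed adjusted over the list alone, camera adjusted p = 0.15). Of 19 acute phase genes 10 fell, with the serum amyloid Saa4 at -2.97 ± 0.11, and 8 rose, with Mt2 at 3.93 ± 0.16 (18 passed adjusted over the list alone, camera adjusted p = 0.64).

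Sex-biased genes moved away from the male state in knockout males. All 23 measured male-biased genes fell (23 passed adjusted over the list alone). The major urinary protein Mup3 stood at -5.50 ± 0.08, the organic anion transporter Slco1a1 at -5.38 ± 0.08 and Ugt2b1 at -4.68 ± 0.09 (camera adjusted p = 1.5e-14, and adjusted p = 0.026 with an estimated correlation). Of 26 female-biased genes 22 rose and 3 fell (25 passed adjusted over the list alone), with Slc22a26 at 4.41 ± 0.11, the oestrogen sulfotransferase Sult1e1 at 3.40 ± 0.08 and the hepcidin gene Hamp2 at 2.55 ± 0.07 (camera adjusted p = 5.1e-07, and adjusted p = 0.085 with an estimated correlation). Both list medians had the same sign on 4 of 4 arrays.

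Genes of fatty acid oxidation and of the cell cycle rose in knockout males. Of 18 PPARA targets and oxidation genes 12 rose and 4 fell (17 passed adjusted over the list alone). The pyruvate dehydrogenase kinase Pdk4 stood at 4.47 ± 0.31, the thioesterase Acot1 at 3.45 ± 0.23 and Ehhadh at 1.41 ± 0.10 (camera adjusted p = 0.0076, and adjusted p = 0.60 with an estimated correlation). Of 24 cell cycle genes 11 rose and 1 fell (12 passed adjusted over the list alone), with Ccnd1 at 1.87 ± 0.19 and the anaphase activator Cdc20 at 1.18 ± 0.19 (camera adjusted p = 0.011, and adjusted p = 0.64 with an estimated correlation). Of 8 cholangiocyte markers 5 rose and 0 fell (5 passed adjusted over the list alone). Prom1 stood at 2.84 ± 0.19 and the transcription factor Sox9 at 2.68 ± 0.14 (camera adjusted p = 0.035, 0.059 with the other pairing, and adjusted p = 0.47 with an estimated correlation). Of 13 fetal and tumour-associated genes 4 rose, the trefoil factor Tff3 by 2.34 ± 0.51 and H19 by 0.54 ± 0.08 among them, and 0 fell (4 passed adjusted over the list alone, camera adjusted p = 0.14, and 0.035 with the other pairing).

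Beside Mup3 and Slco1a1, the largest falls of single genes in knockout males were those of Mup6 (-6.94 ± 0.13, adjusted p = 1.0e-07), Wfdc21 (-5.75 ± 0.32), the NADPH oxidase Nox4 (-5.49 ± 0.09) and Mup5 (-5.42 ± 0.11). Beside Pdk4 and Slc22a26, the largest rises were those of Hao2 (5.43 ± 0.21, adjusted p = 1.55e-06), the defensin Defb1 (5.20 ± 0.12), the stress response gene Gadd45b (5.16 ± 0.32) and Sult2a2 (4.39 ± 0.18). Plppr1 was at least 3.14-fold and Myo5c at least 2.19-fold higher, and Olfr914 at least 2.84-fold and Fam243 at least 1.81-fold lower, each against a level not above background. In all, 11242 of 22031 items passed in males, 5434 higher and 5808 lower in the knockout, and 1721 changed at least 2-fold (620 and 1101). Higher were 48.3% of those that passed, and 60.5% with median centring, which also raised the median of all genes to 0.11. In the same comparison, skeletal muscle transcripts had a median of 0.73, with 11 higher and 3 lower of 15.

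The effect of the knockout in females asks the same of the female liver, and most of the groups that fell in males fell here too. Of 18 complement genes 15 fell and 0 rose (15 passed adjusted over the list alone), with C8a at -4.17 ± 0.08 (camera adjusted p = 8.9e-09, and adjusted p = 0.17 with an estimated correlation). Of 17 lipid transport genes 13 fell and 2 rose (15 passed adjusted over the list alone). Apom stood at -3.11 ± 0.05 and Apoa2 at -2.87 ± 0.08 (camera adjusted p = 4.2e-05, and adjusted p = 0.12 with an estimated correlation). Of 20 genes of amino acid catabolism 14 fell and 1 rose (15 passed adjusted over the list alone), with Haao at -2.93 ± 0.10 (camera adjusted p = 2.5e-05, and adjusted p = 0.46 with an estimated correlation). Of 21 bile acid genes 14 fell and 3 rose (17 passed adjusted over the list alone). Baat stood at -4.21 ± 0.11 and the bile acid importer Slc10a1 at -2.09 ± 0.10 (camera adjusted p = 0.00086, and adjusted p = 0.46 with an estimated correlation). Of 19 coagulation genes 12 fell and 5 rose (17 passed adjusted over the list alone), with F13b at -3.26 ± 0.09 (camera adjusted p = 0.036, and adjusted p = 0.31 with an estimated correlation). Of 17 liver-enriched transcription factors 12 fell and 1 rose (13 passed adjusted over the list alone). Nr1i3 stood at -3.47 ± 0.08 (camera adjusted p = 0.00086, and adjusted p = 0.31 with an estimated correlation). Of 12 genes of glucose handling 8 fell and 0 rose (9 passed adjusted over the list alone), with Gys2 at -3.68 ± 0.12 (camera adjusted p = 0.00086, and adjusted p = 0.17 with an estimated correlation).

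Lipid synthesis fell and oxidation and cell cycle genes rose in knockout females. Of 18 genes of cholesterol biosynthesis 12 fell and 0 rose (13 passed adjusted over the list alone). Insig1 stood at -2.10 ± 0.15 (camera adjusted p = 0.00076, and adjusted p = 0.53 with an estimated correlation). Of 16 genes of fatty acid synthesis 10 fell and 1 rose (12 passed adjusted over the list alone), with the fatty acid synthase Fasn at -1.81 ± 0.15 (camera adjusted p = 0.0062, and adjusted p = 0.52 with an estimated correlation). Of 7 urea cycle genes 5 fell and 1 rose (6 passed adjusted over the list alone). Otc stood at -4.07 ± 0.11 (camera adjusted p = 0.036, and adjusted p = 0.48 with an estimated correlation). Of 18 PPARA targets and oxidation genes 12 rose and 2 fell (16 passed adjusted over the list alone), with Acot1 at 2.81 ± 0.23 and the lipid droplet protein Plin2 at 1.18 ± 0.10 (camera adjusted p = 0.0071, and adjusted p = 0.52 with an estimated correlation). Of 24 cell cycle genes 15 rose and 2 fell (17 passed adjusted over the list alone). Cdc20 stood at 2.43 ± 0.19, Bub1 at 1.48 ± 0.13 and Top2a at 1.15 ± 0.12 (camera adjusted p = 0.00076, and adjusted p = 0.52 with an estimated correlation). Of 13 fetal and tumour-associated genes 5 rose and 0 fell (7 passed adjusted over the list alone), with Tff3 at 2.17 ± 0.51 (camera adjusted p = 0.043, and adjusted p = 0.48 with an estimated correlation). Of 8 cholangiocyte markers 3 rose, Sox9 by 3.21 ± 0.14 and Prom1 by 2.18 ± 0.19 among them (3 passed adjusted over the list alone, camera adjusted p = 0.051, and 0.047 with the pair as a block).

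Male-biased genes fell and female-biased genes moved in both directions in knockout females. Of 23 male-biased genes 19 fell and 1 rose (20 passed adjusted over the list alone). Slco1a1 stood at -5.11 ± 0.08 and Mup3 at -5.06 ± 0.08 (camera adjusted p = 8.9e-09, and adjusted p = 0.074 with an estimated correlation). Of 26 female-biased genes 13 fell, with A1bg at -3.88 ± 0.12, and 8 rose, with Sult1e1 at 3.16 ± 0.08 and the fatty acid transporter Cd36 at 2.58 ± 0.11 (23 passed adjusted over the list alone, camera adjusted p = 0.32). Of 16 genes of the growth hormone and STAT5 list 8 fell and 1 rose (9 passed adjusted over the list alone), with the growth hormone receptor Ghr at -1.60 ± 0.07, Igf1 at -1.56 ± 0.12 and Esr1 at -1.35 ± 0.25 (camera adjusted p = 0.036, and adjusted p = 0.46 with an estimated correlation). In males 6 genes of this list fell and 2 rose (8 passed adjusted over the list alone). Ghr stood at -2.19 ± 0.07 and Igf1 at -2.06 ± 0.12 (camera adjusted p = 0.25). Of 23 conjugation genes 11 fell and 4 rose in females (16 passed adjusted over the list alone), with Sult1b1 at -4.28 ± 0.14 (camera adjusted p = 0.044, 0.051 with the slide as a block, 0.077 with the other pairing, and adjusted p = 0.52 with an estimated correlation).

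Beside Slco1a1, the largest falls of single genes in knockout females were those of Sult3a1 (-6.65 ± 0.35), Mup6 (-6.16 ± 0.13, adjusted p = 2.5e-07), Wfdc21 (-5.47 ± 0.32) and the cytochromes Cyp2c54 (-5.34 ± 0.11) and Cyp2c23 (-5.08 ± 0.08). Beside Sox9, the largest rises were those of Pdk4 (4.48 ± 0.31), Epdr1 (3.59 ± 0.12), the pancreatic enzymes Cela3b (3.47 ± 0.69) and Pnliprp1 (3.34 ± 0.20), and Nat8 (3.29 ± 0.18). Cela3b was raised on all 4 arrays, from 2.11 to 4.60, and Pnliprp1 from 2.76 to 3.91, beside the pancreas list median of 1.31 that came from arrays 3 and 4. None of the 15 pancreas transcripts of that list passed the test, in which arrays 3 and 4 form 1 pair. The list of pancreas markers (5 measured) had a camera adjusted p of 0.49 with these pairs and of 0.0079 with the other pairing. For these markers it went from 0.14 to 8.6e-08 between knockout males and females, and from 0.48 to 0.00015 in the interaction. Smim43 was at least 1.89-fold and Tmigd1 at least 1.87-fold higher, and Serpina3a at least 1.27-fold and Tnfaip8l3 at least 1.21-fold lower, each against a level not above background. Xist rose by 0.89 ± 0.16 in knockout females (adjusted p = 0.0037). In all, 10190 of 22031 items passed in females, 5248 higher and 4942 lower in the knockout, and 1404 changed at least 2-fold (510 and 894). Higher were 51.5% of those that passed, and 63.7% with median centring, which also raised the median of all genes to 0.10.

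The knockout changed largely the same genes in both sexes. Across 22031 items the effects in males and females had a Pearson correlation of 0.871 and a Spearman correlation of 0.807, and Pearson correlations of 0.83 and 0.85 on the single pairs. The genes are not independent replicates, and the 2 effects share no RNA group. Both comparisons held 3944 items that rose in both sexes, where independent lists would share 1294, and 3858 that fell in both, where 1303 would be shared. In opposite directions were 61 and 41 items, where 1219 and 1384 would be shared. Over the 13528 items that passed in at least 1 sex, the median size of the change was 0.355 in males (0.355 and 0.358 on the pairs) and 0.318 in females (0.306 and 0.334).

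**Figure D2:**
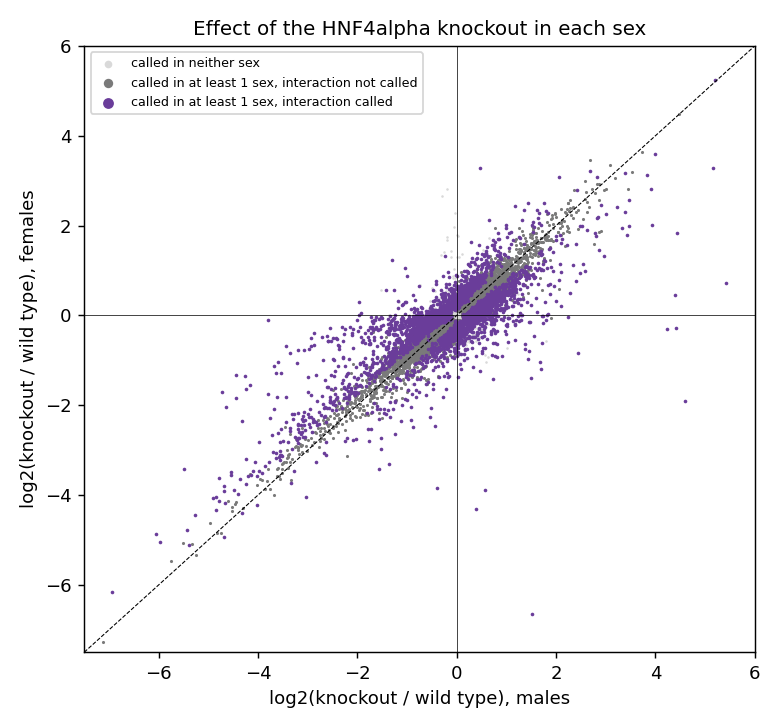
Log2 ratio of knockout over wild type in males (x axis) against females (y axis) for each item tested, with the dashed line marking equal effects. Most items follow the line (Pearson correlation 0.871 across items), and those with an interaction (purple) spread away from it.

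The comparison of knockout males with knockout females asks which sex differences exist without HNF4alpha. The Y-linked genes and Xist differed in the same direction as in wild type, while few of the sex-biased liver genes did. Eif2s3y (6.78 ± 0.15, adjusted p = 3.6e-06), Uty (4.08 ± 0.24, with females well above background on 1 of 4 arrays) and Kdm5d (3.91 ± 0.13) were higher and Xist (-6.61 ± 0.16) lower in males, and the sex chromosome list had 3 genes higher and 4 lower of 8 (8 passed adjusted over the list alone, camera adjusted p = 0.49, and 0.00027 with the slide as a block, with a median of -0.31 and a mean of 0.80). Of 23 male-biased genes 6 were higher in knockout males, Mup3 (1.63 ± 0.08) and Cyp4a12a (1.16 ± 0.14) among them, and 1 was lower (9 passed adjusted over the list alone, camera adjusted p = 0.00028, and adjusted p = 0.16 with an estimated correlation). Of 26 female-biased genes 4 were lower in males and 1 higher (8 passed adjusted over the list alone, camera adjusted p = 0.39). A1bg (-2.65 ± 0.12), Slc22a26 (-0.78 ± 0.11) and Sult3a1 (-2.29 ± 0.35, adjusted p = 0.022, and 0.055 with the pair as a block) were lower in males. For A1bg and Sult3a1 the other comparisons gave another picture. Their interaction was 1.67 and 5.64 from the male against female arrays, but 4.46 and 8.17 from the wild type against knockout arrays. With the latter values little of their wild-type difference would remain, so the size of these 2 knockout sex differences is uncertain.

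Cell cycle genes, and some genes of the growth hormone and STAT5 list, were higher in knockout females. Of 24 cell cycle genes 11 were lower in males and 0 higher (13 passed adjusted over the list alone). Cdc20 stood at -1.65 ± 0.19, the mitotic kinases Bub1 at -1.06 ± 0.13 and Plk1 at -0.79 ± 0.08, and the list median was negative on 4 of 4 arrays (camera adjusted p = 6.0e-12, and adjusted p = 0.36 with an estimated correlation). Ect2, which acts in cytokinesis, was also lower in males (-1.53 ± 0.19). Of 16 growth hormone and STAT5 genes 4 were lower in males and 1 higher (7 passed adjusted over the list alone), with Igf1 at -0.89 ± 0.12 and Igfals at -0.79 ± 0.05 (camera adjusted p = 0.025, 0.11 without the 2 genes it shares with the sex-biased lists, and adjusted p = 0.36 with an estimated correlation). The deiodinase Dio1 (-1.72 ± 0.05, adjusted p = 9.3e-06) was lower in knockout males. Of 19 coagulation genes 3 were lower in males (11 passed adjusted over the list alone). Serpinf2 stood at -0.81 ± 0.07 and F11 at -0.78 ± 0.09, and the list median was negative on 3 of 4 arrays (camera adjusted p = 1.5e-08, and adjusted p = 0.082 with an estimated correlation). Of 10 general hepatocyte markers 4 were lower in males (7 passed adjusted over the list alone), with Ttr at -0.67 ± 0.09, but the list median was negative on only 2 of 4 arrays (camera adjusted p = 0.00017, and adjusted p = 0.27 with an estimated correlation). Apom (-0.73 ± 0.05) was lower among 17 lipid transport genes (1 passed adjusted over the list alone, camera adjusted p = 0.027, and adjusted p = 0.34 with an estimated correlation), with a negative list median on 2 of 4 arrays. Elovl5 (-0.74 ± 0.09) and Mlxipl (-0.51 ± 0.10) were lower among 16 genes of fatty acid synthesis (5 passed adjusted over the list alone, camera adjusted p = 0.041, 0.075 with the slide as a block, 0.070 with the other pairing, and adjusted p = 0.67 with an estimated correlation).

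Skeletal muscle genes were among the largest differences in which knockout males exceeded knockout females. The myosins Myh4 (2.44 ± 0.10) and Myl1 (2.29 ± 0.07) and the muscle cytochrome oxidase subunit Cox8b (2.11 ± 0.09) passed the test, and Myot was at least 3.67-fold higher. With the other pairing, their adjusted p-values were 0.081 for Myh4, 0.099 for Myl1, 0.21 for Cox8b and 0.19 for Myot, and with the slide as a block 0.059 for Cox8b and 0.054 for Myot. Myh4 was at 3.87 and 3.81 on arrays 2 and 3, where the muscle list stood out, and at 1.25 and 0.84 on arrays 1 and 4. The muscle list had 12 of 15 genes higher in knockout males, with a median of 1.11. No adipocyte marker passed in 5 measured (3 adjusted over the list alone), while the list median was 0.37 (camera adjusted p = 0.019, and adjusted p = 0.67 with an estimated correlation).

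In all, 529 of 22031 items differed between knockout males and females, 224 higher and 305 lower in males, and 103 differed at least 2-fold (48 and 55). With the slide as a block 2153 passed, in a fit of this comparison alone 86, and 367 passed with both pairings. The count was 333 without wild-type male against wild-type female replicate 2, 309 without knockout male against knockout female replicate 2, and 287 without wild-type female against knockout female replicate 2. Of the 103 items, 65 did not pass in wild type, 25 of them higher and 40 lower in knockout males. Of these 65, 8 were on the skeletal muscle list, which does not hold the muscle genes Myh4, Myl1, Cox8b and Myot. On the pancreas lists were 0 of them, but arrays 3 and 4, with the pancreas transcripts, form 1 pair. No transcript of the later pancreas list passed in this comparison despite a median of -1.39, so the 0 does not show that pancreas transcripts are absent. An interaction in the knockout direction was found for 36 of the 65 from the wild type against knockout arrays alone. These share no array with the choice of the items, but they hold the same knockout RNA groups, whose deviations correlated by replicate number. The 36 are therefore not an independent count.

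The interaction asks which knockout effects differ between males and females. The sex-biased lists led it, each against its wild-type direction. Of 26 female-biased genes 25 had a more positive knockout effect in males and 0 a more negative one (25 passed adjusted over the list alone). Slc22a26 stood at 4.48 ± 0.11, Hamp2 at 1.65 ± 0.07 and Trim24 at 1.29 ± 0.05 (camera adjusted p = 4.7e-25, and adjusted p = 0.012 with an estimated correlation). Of 23 male-biased genes 20 had a more negative effect in males and 0 a more positive one (22 passed adjusted over the list alone), with Cyp7b1 at -2.92 ± 0.13, Cspg5 at -2.66 ± 0.08 (well above background on 1 of 4 arrays in 1 group) and C6 at -2.40 ± 0.08 (camera adjusted p = 1.2e-17, and adjusted p = 0.012 with an estimated correlation). Beside Slc22a26, the largest positive values were those of Sult3a1 (6.91 ± 0.35, adjusted p = 6.5e-05), Hao2 (4.78 ± 0.21), Sult2a4 (4.22 ± 0.33), Sult2a2 (4.00 ± 0.18) and Slc22a29 (3.45 ± 0.13). On the other side, beside Cyp7b1 and Cspg5, stood Nat8f5 (-3.58 ± 0.16, adjusted p = 4.2e-05), Nat8 (-2.98 ± 0.18), Pate5 (-2.57 ± 0.28) and the steroid dehydrogenase Hsd3b4 (-2.57 ± 0.16). The value of Sult3a1 is the mean of estimates that lay apart, 5.64 from the male against female arrays and 8.17 from the wild type against knockout arrays.

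Other lists also responded unequally. Of 18 complement genes 11 had a more negative effect in males and 1 a more positive one (16 passed adjusted over the list alone). The terminal component C8a stood at -0.80 ± 0.08 and Hc at -0.94 ± 0.09 (camera adjusted p = 0.00080, and adjusted p = 0.40 with an estimated correlation). Without the 2 genes it shares with the sex-biased lists, complement had 9 of 16 more negative and 1 more positive (14 passed adjusted over the list alone, camera adjusted p = 0.017, and adjusted p = 0.46 with an estimated correlation). Of 19 coagulation genes 8 were more negative in males and 0 more positive (10 passed adjusted over the list alone), with F11 at -1.08 ± 0.09 and Serpinf2 at -0.88 ± 0.07 (camera adjusted p = 8.0e-05, and adjusted p = 0.086 with an estimated correlation). Of 17 lipid transport genes 4 were more negative and 0 more positive (5 passed adjusted over the list alone). Apom stood at -0.46 ± 0.05 (camera adjusted p = 0.022, 0.059 with the slide as a block, and adjusted p = 0.30 with an estimated correlation), and the list median from the wild type against knockout arrays was negative at 2 of 4 replicate numbers. Of 10 general hepatocyte markers 5 were more negative and 1 more positive (6 passed adjusted over the list alone), with Ttr at -0.81 ± 0.09 (camera adjusted p = 0.022, and adjusted p = 0.40 with an estimated correlation). The list median of these markers was 0.24, -0.97, 0.22 and -0.86 at the 4 replicate numbers. Its sign thus followed the dye direction, which replicates 1 and 3 of a comparison share and replicates 2 and 4 have turned. Each pair averages both directions, and a dye effect on this list was not tested. Of 12 macrophage markers 4 were more positive in males and 0 more negative (7 passed adjusted over the list alone). Cd163 stood at 0.67 ± 0.10 and Cd5l at 0.36 ± 0.10 (camera adjusted p = 0.0041, and adjusted p = 0.95 with an estimated correlation). Of 13 lymphocyte markers 5 were more positive and 0 more negative (9 passed adjusted over the list alone), with Ccl5 at 1.42 ± 0.22 and Cd3d at 0.47 ± 0.08 (camera adjusted p = 0.062, 0.019 with the slide as a block, and 0.012 with the other pairing). Of 24 cell cycle genes 10 were more negative and 2 more positive in males (14 passed adjusted over the list alone). Cdc20 stood at -1.33 ± 0.19, the cyclin Ccnb2 at -0.94 ± 0.13 and Ccnd1 at 1.29 ± 0.19 (camera adjusted p = 0.053, and 0.025 with the other pairing). The muscle transcripts had 11 of 15 genes with a more positive value in males and a median of 0.98.

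In all, 3816 of 22031 items had an interaction, 1661 with a more positive and 2155 with a more negative knockout effect in males, and 315 at least 2-fold (145 and 170). The count was 1044 from the male against female arrays, 1168 from the wild type against knockout arrays and 917 in a fit of the interaction alone. With the slide as a block it was 7048, and 3393 passed with both pairings. More positive in males were 43.5% of those that passed, and 55.7% with median centring. An interaction was found for 1568 of the 7802 items that changed in the same direction in both sexes and for all 102 that changed in opposite directions. The latter count is nearly fixed by the choice of these items, since opposite changes that both passed add up in the interaction. It was found for 1239 of the 3338 that passed in males alone and for 681 of the 2286 that passed in females alone.

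Most genes with a sex difference in wild type lost it in the knockout. Of the 252 items that differed at least 2-fold between wild-type males and females, 230 had an interaction against their wild-type direction and 5 along it. From the wild type against knockout arrays alone, 188 had an interaction against it. These arrays share no array with the choice of the items, but they hold the same wild-type RNA groups, whose deviations correlated by replicate number. The 188 are therefore not an independent count. A sex difference in the same direction passed for 44 of the 252 in the knockout. The 157 male-biased items had a median difference of 1.40 in wild type and 0.08 in the knockout, and 147 of them fell in knockout males and 117 in knockout females (medians of -2.29 and -0.59). The 95 female-biased items had a median difference of -1.44 in wild type and -0.12 in the knockout. Of these, 60 rose and 20 fell in knockout males (median 0.78), while 24 rose and 54 fell in knockout females (median -0.63).

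**Figure D3:**
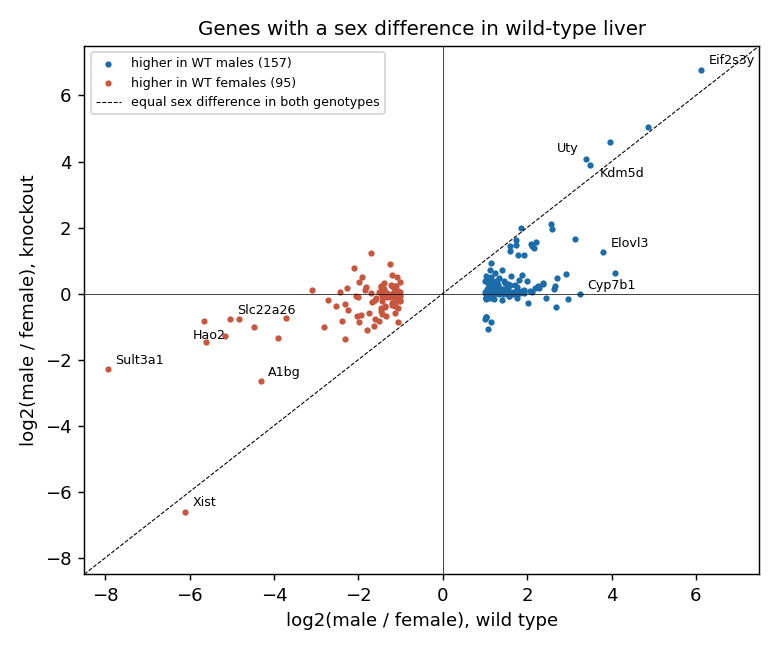
Log2 ratio of male over female in wild type (x axis) against the knockout (y axis) for the 252 items with at least a 2-fold sex difference in wild type. Most lie near 0 on the y axis (medians of 0.08 for the 157 male-biased and -0.12 for the 95 female-biased items), while Xist and the Y-linked genes lie near the dashed line of equal differences.

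**Figure D4:**
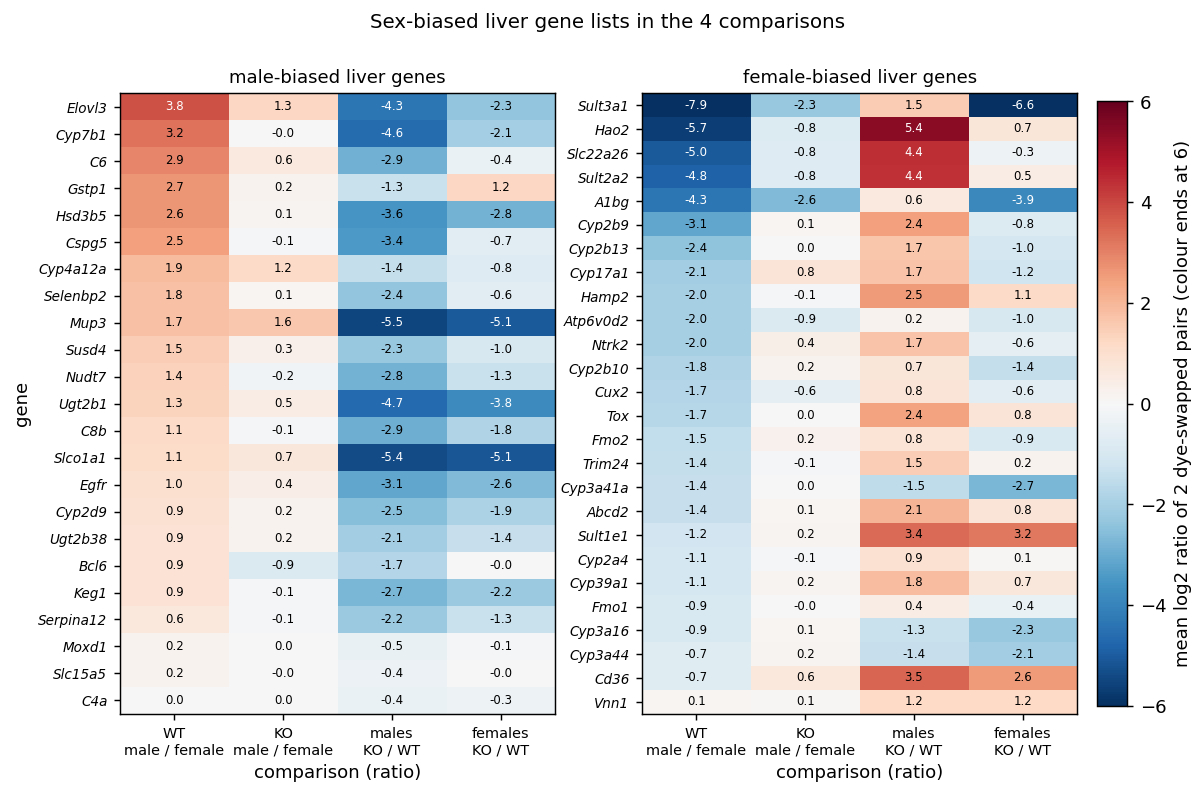
Mean log2 ratio of the measured genes of the male-biased list (left, 23 genes) and of the female-biased list (right, 26 genes) in the 4 comparisons, with the colour scale ending at 6. All 23 male-biased genes fell in knockout males and 19 in knockout females, while 22 of 26 female-biased genes rose in knockout males.

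The knockout effect in males tended to run against the wild-type sex difference. Across items, the wild-type sex difference and the knockout effect in males had a Pearson correlation of -0.418. These comparisons share wild-type male RNA, and simulated groups without any change gave -0.446, but with a covariance of -0.00599 against -0.0814 in the data. With values from different pairs the correlations were -0.359 and -0.357. With the knockout effect in females the correlation was -0.068 and the covariance -0.0118, against 0.440 and 0.00589 in simulated groups that share wild-type female RNA (-0.126 and -0.055 with values from different pairs). The sex differences of wild type and knockout had a correlation of 0.301 across items (Spearman 0.173), and 148 items passed in both, where 55.8 would be shared.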

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

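The comparisons, the gene lists other than those of skeletal muscle and of further pancreas transcripts, the rule for naming genes and the processing alternatives, except those stated to have been added later, were chosen before the data were examined. The tests of muscle transcripts on arrays 2 and 3, of the immune cell lists in the knockout effect in females and of the lymphocyte list in the knockout sex difference, were chosen only after the result they measure was seen.

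Transcripts of skeletal muscle and pancreas were higher in knockout RNA of some arrays. The lowest muscle median on any array of the comparison of knockout males with knockout females was 0.20, while on arrays 2 and 3 of both comparisons with knockout male RNA it was at least 1.42, so muscle tissue in the knockout male RNA of arrays 2 and 3 is a candidate explanation. For muscle in all knockout male pools, the lower of the 2 comparison medians, 0.73, lay between the bounds set. It averages all 4 arrays and so cannot decide this. On arrays 1 and 4 the medians were 0.20 and 0.22 against knockout females, and 0.20 and -0.01 against wild-type males. This argues against a like amount of muscle on all arrays. A smaller amount stays open, since single genes were raised there, with Myh1 at 0.60 and 0.78 against knockout females and 1.06 and 0.72 against wild-type males. Pancreas transcripts had a median of at least 2.37 on arrays 3 and 4 of the knockout effect in females and of at most -0.0022 on arrays 1 and 2. This argues against a rise of this list in all knockout female pools and leaves pancreas tissue in the RNA of arrays 3 and 4 as a candidate explanation. The pancreatic enzymes Cela3b and Pnliprp1, which are not on this list, were raised on all 4 arrays. Pancreas tissue on arrays 3 and 4 alone would not account for these 2 genes. How the pools were dissected is not given, and a biological cause was not tested.

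Genes with a sex difference in wild type lost it in the knockout. Of the 230 items concerned, 87.8% (202) were well above background in both channels on all 4 arrays of knockout male against knockout female. The Y-linked Eif2s3y and Kdm5d, however, were also called well above background in knockout females on all 4 of these arrays. This call therefore does not show specific signal, and it cannot decide whether ratios near background were compressed. Selection of items for a large wild-type difference is argued against. Of the 297 items at least 2-fold on pair 1 of the wild-type comparison, 85.9% (255) had an interaction against it on pair 2 of the wild type against knockout arrays, with a median of -1.07. Dependence of the sex differences on HNF4alpha may explain this, as a hypothesis found and tested on the same data, while hormone levels and the state of the knockout liver were not measured and stay open.

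Cell cycle genes were higher in the knockout and higher in knockout females than in knockout males. For the rise in knockout females, more immune cells are argued against, since the highest median of the lymphocyte, macrophage and neutrophil lists in the knockout effect in females was -0.15, where the cell cycle median was 0.85. Against knockout males, lymphocytes stay open, since their list was also higher in knockout females on 4 of 4 arrays. The lymphocyte median was -0.12, however, against -0.65 for the cell cycle. Of 12 macrophage markers 3 rose in knockout males (0 passed adjusted over the list alone), and 0 passed between knockout males and females. The 2 arrays flagged for their spots are argued against, since 11 cell cycle genes were lower in knockout males without them too. The cell cycle list was also lower in wild-type males, with a median of -0.29 (camera adjusted p = 9.5e-05, and 0.94 with an estimated correlation). Its interaction had a camera adjusted p of 0.053, so a sex difference that arises only after loss of HNF4alpha is not shown. A sex difference in proliferation may explain the pattern, as a hypothesis, and a different course of liver damage was not tested.

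The sign patterns of the 4 arrays of a comparison, the real one included, number 8, which is too few for a share under 0.05. The real pattern called 2323 items for the wild-type sex difference (highest other 42), 529 for the knockout sex difference (78), 11242 for the knockout effect in males (42) and 10190 for that in females (64), and in each comparison 1 pattern, the real one, called as many. With the male against female arrays as separate samples, 1 of 35 splits, the real one, called as many as 2029 items, and the highest other called 149. With the wild type against knockout arrays it was 1 of 35, with 1716 items against 223. The replicate numbers link the arrays, however, and the splits that part all 4 numbers are 8, too few for a share under 0.05, with 0 and 223 items for the highest other.

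Single arrays lay apart from the other 3 of their comparison in 7 of 79 groups, where chance flags about 1 in 20 groups, or 3.95. Replicate 1 of knockout male against knockout female had 92.1% of spots well above background over both channels. Replicate 1 of wild-type female against knockout female had 1338 outlier spots. Sult2a2 was at -4.38 on replicate 2 of wild-type male against wild-type female. On the knockout male against knockout female arrays, Kdm5d was at 3.21 on replicate 1 and Ect2 at -2.00 on replicate 2. Cyp2c54 was at -5.76 on replicate 3 of the knockout effect in females. Uty was at 0.84 on replicate 4 of the knockout effect in males.

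The knockout effect differed between males and females by the interaction test for 38 of the genes named for the size of their change or in every case, without the members named from lists. It was more positive in males for Sult3a1 (6.91), Hao2 (4.78), Slc22a26 (4.48), Sult2a4 (4.22), Sult2a2 (4.00), Slc22a29 (3.45), A1bg (3.06), Gadd45b (2.17), Epdr1 (0.59), Kdm5d (0.50) and Eif2s3y (0.60). Defb1 passed at 0.63, but its estimates had opposite signs, with 1.31 from the male against female arrays and -0.045 from the wild type against knockout arrays. The estimates also lay apart for Sult3a1 (5.64 and 8.17, in the same order) and A1bg (1.67 and 4.46). The muscle genes Myh4 (2.32), Myl1 (2.01), Cox8b (2.00) and Myot (1.89) were also more positive in males. It was more negative in males for Nat8f5 (-3.58), Nat8 (-2.98), Cyp7b1 (-2.92), Cspg5 (-2.66), Pate5 (-2.57), Hsd3b4 (-2.57), Elovl3 (-2.26), Nox4 (-2.07), Olfr914 (-1.44), Cdc20 (-1.33) and Dio1 (-1.20). Smaller negative values were those of Xist (-0.64), Mup5 (-0.64), Smim43 (-0.64), Fam243 (-0.63), Sox9 (-0.56), Myo5c (-0.56), Mup6 (-0.55), Trav14d-3-dv8 (-0.48), Plppr1 (-0.46), Slc35f1 (-0.43) and Slco1a1 (-0.34). Kdm5d, A1bg, Myot, Trav14d-3-dv8, Slc35f1, Plppr1, Myo5c, Olfr914, Fam243 and Smim43 were well above background on 0 of 4 arrays in at least 1 group, and Eif2s3y, Xist, Myh4, Nox4 and Cspg5 on 1, so their values depend on levels near background and are not exact differences. With the other pairing 7 of the 38 no longer passed, with adjusted p-values of 0.052 for Eif2s3y, 0.064 for Myl1, 0.13 for Cox8b, 0.11 for Myot, 0.20 for Mup6, 0.13 for Sox9 and 0.53 for Slco1a1. Of 100 interaction values that passed for named genes and list members, 36 no longer passed on the male against female arrays alone. On the wild type against knockout arrays alone 37 no longer passed, and 0 reversed on either kind.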

How the results depend on the processing

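A fit of each comparison alone and leaving out both arrays flagged for their spots were tests chosen only after the data were seen. So were requiring a call with both pairings and lists without the genes shared with the sex-biased lists. Counts below are for the wild-type sex difference, the knockout sex difference and the interaction, in this order, unless other results are named. Where a value changed, the cause was not tested.

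The counts of 2323, 529 and 3816 rose when arrays were used as separate replicates (4449, 1525 and 5946), with the slide as a block (5584, 2153 and 7048), with a dye term (5401, 2145 and 6924), in a loop model (6136, 3058 and 6304), with the slide as a random block (4495, 1506 and 5977) and with the other pairing of arrays (4160, 1226 and 5780). They fell to 1455, 86 and 917 when each was fitted alone. The interaction fell to 1044 on the male against female arrays and to 1168 on the wild type against knockout arrays. With at least 1.5-fold required, the counts were 593, 252 and 889, with 3807 for the knockout effect in males and 3255 in females. With an unadjusted p under 0.0001 and at least 1.5-fold they were 362, 135 and 472, with 2859 and 2367.

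Sex-biased items with an interaction against their wild-type direction, 230 of 252, became 511 of 594 with Agilent's own ratios, 498 of 582 with the authors' matrix values, 141 of 158 without background subtraction and 1681 of 2323 without a fold minimum. The correlation of the knockout effects in both sexes, 0.871, was 0.825 with Agilent's own ratios and 0.821 with the matrix values. Of 155 list tests, 57 passed, with 56 without the genes shared with the sex-biased lists and 5 with an estimated correlation between genes.

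Leaving out each array in turn gave 1651 to 2844 items for the wild-type sex difference, 287 to 605 for the knockout sex difference, 10204 to 11462 and 9156 to 10411 for the knockout effect in males and females, and 2695 to 4095 for the interaction. It gave 52 to 61 list calls, 199 to 259 sex-biased items and correlations of 0.859 to 0.875. The knockout sex difference moved by over 1.5 times without replicate 2 of wild-type male against wild-type female (333), of knockout male against knockout female (309) and of wild-type female against knockout female (287).

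Of 16820 gene values under the alternatives, 15811 passed in the same direction, 1002 no longer passed and 7 reversed. These values cover only the named genes and list members that passed in the main fit, 475 in most settings. They were chosen for a large change or a small p, so they do not give the stability of all calls. Prom1 went from 0.68 to -0.056 in the interaction without background subtraction. With median centring, Hsd17b4 went from 0.24 to -0.0072 in the wild-type sex difference, Tie1 from -0.18 to 0.16 in knockout males, and Rhbg from -0.23 to 0.12 and Rgs5 from -0.32 to 0.028 in knockout females. Eif2s3x went from -0.61 to 0.30 in the wild-type sex difference with the mean over probes, and leaving out single arrays of that comparison gave Ahsg, at -0.41, values from -0.91 to 0.082 (without replicate 1). The alternatives changed no other of these counts by more than 1.5 times. The probe filter kept 22031 items, against 20469 with a filter in both channels and 28561 with none. Each scan had at least 68.5% of spots well above background, and the number of arrays limits the precision.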

Other observations

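Some genes of iron, blood and other cell types changed with the knockout. Of all items, 51.0% passed in knockout males and 46.3% in knockout females. The neutrophil, endothelial and stellate cell lists below had smaller shares than these. Among erythroid markers in knockout males, Alas2 of haem synthesis stood at -2.55 ± 0.09, the carbonic anhydrase Car1 at -1.84 ± 0.13 and Car2 at 1.31 ± 0.07. Of the 7 markers 3 rose and 3 fell (camera adjusted p = 0.80, with a median of 0.04 and a mean of -0.62). In knockout females 4 rose and 3 fell, with the transcription factor Klf1 at -2.17 ± 0.31 and Car2 at 1.02 ± 0.07 (camera adjusted p = 0.49). Alas2 was higher in wild-type males than in wild-type females (2.02 ± 0.09), and its interaction was -2.29 ± 0.09. The neutrophil receptor Csf3r fell by 1.70 ± 0.09 in knockout males, and the myeloperoxidase gene Mpo by 0.73 ± 0.09 in knockout females, where 2 of 9 neutrophil markers passed in each sex (camera adjusted p = 0.92 and 0.14). Of 13 endothelial markers 2 rose and 1 fell in males and 3 rose in females (camera adjusted p = 0.64 and 0.32), with Lyve1 of the sinusoids at 1.77 ± 0.18 and 1.29 ± 0.18. Of 14 stellate cell markers, 1 rose and 4 fell in males, with the smooth muscle actin Acta2 at 1.33 ± 0.07 (camera adjusted p = 0.72), beside the muscle transcripts on arrays 2 and 3.

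The interaction held regulators of sex-biased expression and stress genes. Of 16 growth hormone and STAT5 genes, 3 were more positive and 3 more negative in males (9 passed adjusted over the list alone, camera adjusted p = 0.80), with the male-biased repressor Bcl6 at -1.72 ± 0.12, the female-biased repressor Cux2 at 1.27 ± 0.18 and Ghr at -0.61 ± 0.07. Of 19 acute phase genes, 7 were more positive and 3 more negative in males, with Mt2 at 2.22 ± 0.16, Orm3 at 1.47 ± 0.13 and the hepcidin gene Hamp at 1.03 ± 0.09 (camera adjusted p = 0.78, with a median of -0.18 and a mean of 0.30). Pnpla3 had an interaction of 2.06 ± 0.13 and the transporter Slco1a4 of 2.41 ± 0.12. Between knockout males and females, Fgf21, a hormone of fasting, was lower in males (-1.48 ± 0.25), and the glycogen synthase Gys2 (0.64 ± 0.12) and the glucose transporter Slc2a2 (0.46 ± 0.09) were higher. The lymphocyte list was lower in knockout males, with Ms4a1 of B cells at -0.64 ± 0.09 (camera adjusted p = 0.027, and adjusted p = 0.36 with an estimated correlation). The endothelial and erythroid lists were lower too, with no gene that passed (camera adjusted p = 0.029 for each, and adjusted p = 0.67 and adjusted p = 0.34 with an estimated correlation).

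The 4 comparisons form a closed loop that the arrays followed across items, though not for every gene, with A1bg, Sult3a1 and Defb1 among the exceptions. The knockout sex difference had a correlation of 0.893 with the sum it should equal from the other 3 comparisons, and the interaction from either kind of array had a correlation of 0.946. The correlation of the 2 pair means was 0.949 and 0.919 for the knockout effects, 0.743 for the wild-type and 0.543 for the knockout sex difference. The deviations of the arrays also followed the replicate number across comparisons that share an RNA group, in 16 of 16 cases.

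By camera 15 and 16 of 31 lists passed for the knockout effect in males and females, 8 and 11 for the sex difference in wild type and knockout, and 7 for the interaction. With an estimated correlation these counts were 1, 0, 2, 0 and 2, and with fry 21, 24, 4, 10 and 9.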
